A study of Mus musculus with 4 samples.

How the data were processed

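S9.6 CUT&Tag was measured in 3 libraries of mouse P19 embryonal carcinoma cells, 1 with a control adenovirus and 1 with each of 2 Ube2t hairpin adenoviruses, and CUT&Tag without primary antibody in 1 library of control cells. Per the labels' protocols, libraries were made with a commercial hyperactive transposase kit and amplified for 11 PCR cycles. Per the submitters' processing notes, Trimmomatic, Bowtie (listed with version 0.7.12), MACS2 2.1.2 and the mm10 build were used. The order of these steps, duplicate handling, fragment filters, the q threshold and the use of a control library in peak calling are not given in the sources used here. PCR duplicates, if kept, would raise the pileup of single sites, and the intervals printed leave this out.

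The deposited files are peak lists, 1 per library, called in each library separately. The authors' fold enrichment of each summit over its local background is a ratio, and the deposited p and q of each summit are on a −log10 scale. Positions are on mm10 and are printed counted from 1. The lowest deposited −log10 q was 1.31 in shCtrl, 1.32 in shUbe2t #1, 1.32 in shUbe2t #2 and 1.31 without antibody. Folds were used to describe, rank or filter peaks within a list. Several summits can share an interval. The 1443, 1683, 1810 and 620 summits of shCtrl, shUbe2t #1, shUbe2t #2 and the no-antibody library gave 1263, 1519, 1640 and 516 distinct intervals, each with the values of its best summit by p.

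Fold and −log10 p were solved together for the summit pileup and the background it was compared with, taking fold as the ratio of both after adding 1 and p as a Poisson tail. In each list at least 99.1% of solved pileups were whole within 0.05, against 9.3% of 1000 simulated pileups that were not whole. At summits with a whole pileup under 100, the 1171, 1460, 1579 and 477 backgrounds clearly above the lowest value were multiples of 0.02 within 0.002, the step of 200 bp fragments counted in 10000 bp of the same library. The values therefore have the form of calls against each library's own surroundings, with no second library scaled in, and the no-antibody library was set against the S9.6 lists only by overlap. The lowest background per library was taken as a measure of depth. It gives depth relative to shCtrl, and the number of fragments per library stays unknown.

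Overlap counted from 1 bp. The S9.6 intervals were merged at 0 bp into regions, and a region held a library when an interval of that library lay in it. A region was near a gene end when it came within 1000 bp of either annotated end of a gene, in a gene body when it otherwise overlapped one, and between genes when it did neither. The table of 49939 placed genes (GRCm38.p6, the same build as mm10) has no strand and no exons. Gene ends therefore stand in for the transcription starts that had been planned, exons and introns were not told apart, and base composition was not computed since no genome sequence was used here. Intervals on the mitochondrial genome (3 per library) and on unplaced sequence entered overlaps and not locations. Random placements (1000 per set) kept each interval's length and chromosome, from 3000000 bp to the last gene or interval of that chromosome, and did not take account of mappability.

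The gene lists were written before the data were examined. They held 428 names, of which 426 matched the gene table, and 407 distinct placed genes. A gene held an interval when one overlapped its body or the 1000 bp beside it. Random lists (10000 per comparison) were matched on gene length in 20 bins. Genes named in the text followed a rule set before the data were examined. It took Ube2t in every library, the 10 genes at knockdown-shared regions free of no-antibody intervals with the highest mean percentile rank of fold in the 2 knockdown lists, the 10 at such control-only regions with the highest shCtrl fold, the 10 at such regions of all 3 libraries with the highest mean rank, the 5 strongest no-antibody intervals by position, and members of the preset lists at knockdown-shared or control-only regions. A region was given to the gene with the nearest end within 1000 bp, otherwise to the longest gene whose body held it. Predicted genes (Gm and Rik names) came after all others, both in giving a region its gene and in the ranking, so that some with higher folds than the genes printed are not named. List members named beside the count of their list for a single library were chosen after their values were seen. Some members of the lists are not reported here by name.

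With 1 library per condition no test between conditions was made. Shares carry exact 95% binomial intervals. Knockdown-shared regions were set beside the same count for the other pairs of libraries. Depth-scaled pileup is the recovered summit pileup divided by the lowest background of its library. The closest call to a threshold was computed from the lowest −log10 p of the library without the call. Alternatives tried were a −log10 q of at least 5, equal list lengths by p, an overlap of 50% of the shorter interval, merging within 1000 bp, removal of intervals overlapping the no-antibody list, chromosomes 1 to 19 and X, windows of 3000 and 500 bp, the summit in place of the interval, gene ends alone for the lists, random lists not matched on length, and each hairpin alone. Protein-coding gene ends, lists matched on length and biotype, depth-scaled pileup and the threshold distance of regions of 1 knockdown library were added after the data were examined. The calculations were tested on simulated data. All of 1000 simulated pileups were recovered within 0.05, and 0 of 1539 simulated regions had a wrong set of libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with a random seed of 1.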

Results

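P19 cells, a mouse embryonal carcinoma line, were profiled by CUT&Tag with S9.6, an antibody against RNA:DNA hybrids. Such hybrids are part of R-loops, structures in which an RNA strand pairs with one DNA strand and displaces the other. The series holds no library in which hybrids had been removed, so the called S9.6 intervals were not shown to be R-loops. In CUT&Tag, a transposase brought to the antibody cuts and tags the DNA around it. The series asks what part UBE2T, the E2 ubiquitin-conjugating enzyme of the Fanconi anaemia pathway, plays in the removal of R-loops. There were 4 libraries, 1 per condition. Cells given a control adenovirus (shCtrl) and cells given either of 2 adenoviruses with different hairpins against Ube2t (shUbe2t #1 and #2) were profiled with S9.6. A further library of shCtrl cells was made without primary antibody, per its label, as the control sample. The deposited peak names of that library begin with IgG, so whether a non-specific antibody was added is not settled here, and "no antibody" follows the label. With 1 library per condition there was no replicate check and no p-value is given. The bounds printed are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. A difference between lists is therefore a difference between these libraries.

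The shCtrl S9.6 list held 1263 called intervals covering 440364 bp, the shUbe2t #1 list 1519 covering 514710 bp, the shUbe2t #2 list 1640 covering 534965 bp, and the no-antibody list 516 covering 194788 bp. The genome-wide background recovered from the deposited values, which scales with the number of fragments, was 1.31 in shCtrl, 1.21 in shUbe2t #1, 1.23 in shUbe2t #2 and 0.772 without antibody. Relative to shCtrl this is a depth of 92.2%, 93.6% and 58.7%. The median summit of the shCtrl list held 17 fragments, for which a Poisson count has a 95% interval of 9.9 to 27.2, so that single regions were measured with low precision. The weakest called summits held 8 fragments in the S9.6 lists and 7 in the no-antibody list.

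Ube2t itself (gene 67196, mm10 chromosome 1, 134962565 to 134974180), the target of both hairpins, held no interval in its body or within 1000 bp of its ends in any of the 4 libraries. The nearest interval lay 226 kb away in each S9.6 library and 256 kb away in the no-antibody library. Peak lists of genomic DNA do not measure the transcript, so the knockdown could not be checked here.

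The first comparison, S9.6 against no antibody, asks which intervals were called with S9.6 and not in the control library. The highest fold in each of the 4 lists was at one site in the body of Chl1, a neural cell adhesion molecule (chromosome 6, 103648978 to 103649382). Its fold enrichment was 43.5 without antibody, against 42.8 in shCtrl, 42.8 in shUbe2t #1 and 42.2 in shUbe2t #2. The local background also counts the fragments of the site itself. Folds of isolated strong sites therefore approach a common limit, and near-equal folds do not mean equal signal per fragment. The next 4 no-antibody intervals by fold, on chromosome X at 143482906 to 143483209, chromosome 9 at 24541917 to 24542259, chromosome 10 at 130594709 to 130595091 and chromosome 12 at 120028598 to 120029020, lay between annotated genes. Their folds were 41.9, 38.9, 36.9 and 36.3 without antibody, and each was also called in all 3 S9.6 libraries with a fold of 33.1 or more. Of the 100 intervals with the highest fold in each S9.6 list, 99 overlapped a no-antibody interval.

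Over whole lists the overlap was smaller. It came to 33.3% of shCtrl intervals (421 of 1263, 30.7 to 36.0), 26.7% of shUbe2t #1 intervals (405 of 1519, 24.5 to 29.0) and 24.5% of shUbe2t #2 intervals (402 of 1640, 22.4 to 26.7). Thinned to the depth of the no-antibody library, 818, 1050 and 1132 of these intervals would be expected to be called. Some intervals free of no-antibody intervals could therefore be missing from that list through its depth alone. In the other direction, 82.4% of the no-antibody intervals were in the shCtrl list (78.8 to 85.6). In 1000 draws, random placement of the shCtrl intervals gave at most 0.251% overlap with the no-antibody list. Random placement of the no-antibody intervals gave at most 0.636% overlap with the shCtrl list. Among intervals with a deposited −log10 q of at least 5, the overlapping share was 53.8% in shCtrl, 43.8% in shUbe2t #1 and 39.6% in shUbe2t #2.

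S9.6 intervals outside the no-antibody list lay at the ends of genes more often than no-antibody intervals or random placements. Outside no-antibody intervals, 46.7% of shCtrl intervals (43.2 to 50.2), 64.4% of shUbe2t #1 intervals (61.5 to 67.3) and 65.9% of shUbe2t #2 intervals (63.2 to 68.6) lay within 1000 bp of an annotated gene end. The no-antibody list reached 14.8% (11.7 to 18.4), and random placement of the same intervals 7.24% on average. Gene bodies held 37.1% of no-antibody intervals against 43.8% at random. Either end of a gene counted, because the annotation used here gives no strand.

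**Figure D1:**
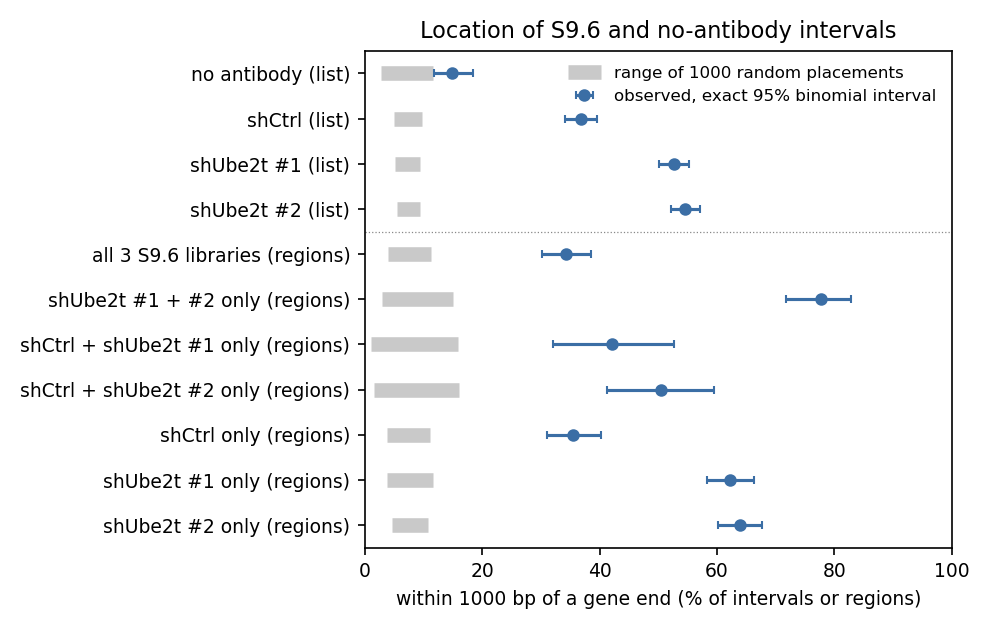
Share of called intervals (upper 4 rows, per library) and of merged regions (lower 7 rows, by the S9.6 libraries that hold them) within 1000 bp of a gene end, in percent on the x axis. Points are observed shares with exact 95% binomial intervals, and grey bars are the range of 1000 random placements. The regions of both knockdown libraries without shCtrl stand highest, at 77.7%, and the no-antibody list lowest, at 14.8%.

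Among regions called in all 3 S9.6 libraries and free of no-antibody intervals, the 10 genes with the highest mean rank of fold, with predicted genes (Gm and Rik names) placed last by the rule and so not reached, are named here. The first was a 265 bp site in the body of Il1rapl1, a synaptic adhesion protein encoded by a very long gene (chromosome X, 87238257 to 87238521), with folds of 20.1 in shCtrl, 25.7 in shUbe2t #1 and 21.9 in shUbe2t #2. Lrp1b, a very large gene of the LDL receptor family, had an intragenic site with folds of 6.91, 7.68 and 7.14 in the same order. The others in gene bodies were in Ppfibp2, Dock2, Peak1, Arhgap21 and the vomeronasal receptor pseudogene Vmn2r-ps17. The 3 that lay at gene ends were at Rnf41, a ubiquitin ligase (8.33, 5.92 and 8.63), at Ap2a1, a subunit of the clathrin adaptor AP-2 (6.12, 6.82 and 7.69), and 746 bp from n-R5s100, a 5S ribosomal RNA gene (9.07, 6.14 and 7.17). The Ap2a1 region was also near an end of Tsks.

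The second comparison, knockdown against control, asks where S9.6 signal was called with Ube2t knocked down and not without, or the reverse. Merging the 3 S9.6 lists gave 2773 regions. Of these, 576 were called in all 3 libraries, and 366 of the 576 overlapped a no-antibody interval. There were 234 regions in both knockdown libraries and not in shCtrl, here called knockdown-shared. The other 2 ways of pairing libraries gave 102 regions in shCtrl and shUbe2t #1 alone and 128 in shCtrl and shUbe2t #2 alone. Regions called in 1 library were more numerous, at 454 in shCtrl (here called control-only), 592 in shUbe2t #1 and 687 in shUbe2t #2. Few of the knockdown-shared regions (10 of 234) or control-only regions (18 of 454) overlapped a no-antibody interval.

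**Figure D2:**
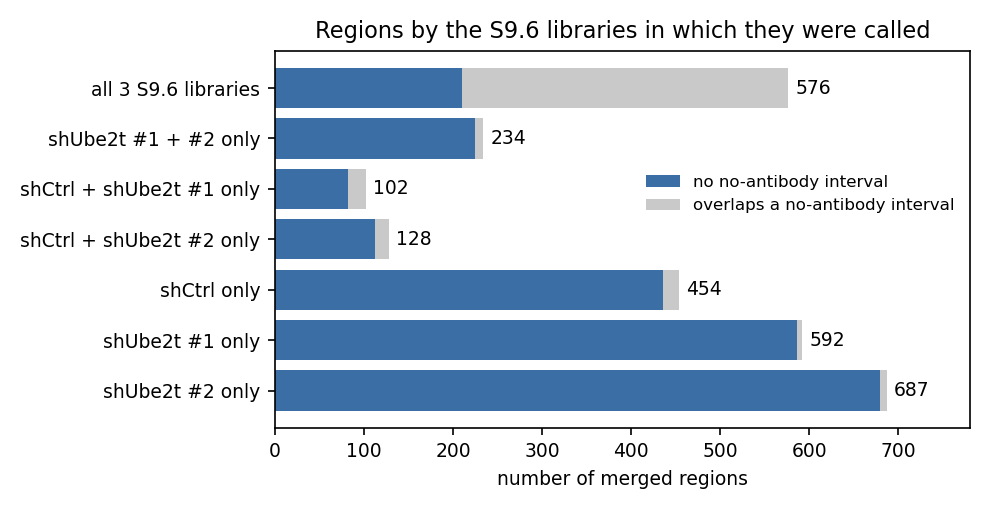
Number of merged regions (x axis) by the S9.6 libraries in which they were called, split into regions with and without a no-antibody interval. The 234 regions of both knockdown libraries without shCtrl outnumber the 102 and 128 of the other pairs, and 366 of the 576 regions of all 3 libraries overlap a no-antibody interval.

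Knockdown-shared regions lay at the ends of genes more often than control-only regions. The shares were 77.7% (181 of 233 on chromosomes 1 to 19, X and Y, 71.8 to 82.9) and 35.5% (157 of 442, 31.1 to 40.2). Regions of shCtrl and shUbe2t #1 alone reached 42.1% (32.0 to 52.7) and those of shCtrl and shUbe2t #2 alone 50.4% (41.3 to 59.5). Regions of shUbe2t #1 alone reached 62.3% (58.2 to 66.2) and those of shUbe2t #2 alone 64.0% (60.2 to 67.6). Random placement of the knockdown-shared regions gave 7.76% on average. The same order appeared in the whole lists, with 36.8% of shCtrl intervals (34.1 to 39.6), 52.6% of shUbe2t #1 intervals (50.04 to 55.2) and 54.6% of shUbe2t #2 intervals (52.1 to 57.1) near gene ends.

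Of the 10 named knockdown-shared regions, 7 were at gene ends. Regions between genes have no gene to name, so this count does not stand for the share of all knockdown-shared regions. At Inpp5f, an inositol phosphatase gene (chromosome 7, 128610999 to 128611416, overlapping the gene end), the fold was 6.78 in shUbe2t #1 and 10.2 in shUbe2t #2. The region 37 bp from Dtl, which encodes the substrate receptor of a ubiquitin ligase that controls replication licensing, was also at an end of Ints7, an Integrator subunit gene (chromosome 1, 191575581 to 191576048), and had folds of 6.69 and 5.30. At Cenpc1, the gene of a centromere protein, the folds were 6.06 and 5.72. Hspbp1, a co-chaperone gene of HSP70, had 7.24 and 5.21, Mex3b, an RNA-binding protein gene, 7.31 and 5.17, Slc35f5 5.66 and 6.21, and Avl9 5.71 and 5.70. The Mex3b region lay 861 bp from the gene and was also near an end of the predicted gene Gm36584. The 3 regions in gene bodies were in Ppp2r3c, which encodes a regulatory subunit of protein phosphatase 2A (6.11 and 8.47), Pkp4, a plakophilin gene (6.50 and 5.74), and Scfd2 (6.30 and 5.67).

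Among the 10 named control-only regions, the highest fold was 7.14 in the body of Cmtm6 (chromosome 9, 114743505 to 114743771). The other 9 lay at gene ends. They included Nr6a1, the gene of the orphan receptor also called germ cell nuclear factor (fold 6.82), Wasf1, an actin regulator gene (6.69), Clcn3, a chloride-proton exchanger gene (6.41), Mcee, which encodes methylmalonyl-CoA epimerase (6.39), the locus LOC115488029 (6.21), and Cox18, a cytochrome oxidase assembly gene (6.16). The Wasf1 region was also within 1000 bp of an end of Cdc40, and the Mcee region of an end of Mphosph10. Myo6, an unconventional myosin gene, had 6.13, the immunoglobulin segment Ighv1-18 6.05, and Lman1, an ER-to-Golgi cargo receptor gene, 5.97. The Ighv1-18 region lay 987 bp from the segment. Regions between genes could not be named here either, so 9 of 10 does not stand for the share of control-only regions at gene ends.

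Summits were set against the calling threshold of the library without the call. For knockdown-shared regions, the median summit of shUbe2t #1 stood 1.41 times above the smallest pileup that would have been called in shCtrl, after scaling for depth, and that of shUbe2t #2 also 1.41 times. The share over 1.5 times was 39.7% and 35.5%. For control-only regions the medians were 1.16 against shUbe2t #1 and 1.17 against shUbe2t #2, and the shares over 1.5 times 11.5% and 12.6%. Regions of 1 knockdown library alone, added after the data were examined, had medians of 1.33 (shUbe2t #1) and 1.36 (shUbe2t #2) and shares of 25.5% and 28.5%. Knockdown-shared regions needed a call in 2 libraries and the others in 1, which by itself selects higher summits, and shCtrl was the deeper library, so the classes cannot be ranked from these values. Counted against shCtrl with 1 hairpin alone, shUbe2t #1 gave 831 regions absent from shCtrl and shUbe2t #2 gave 928. In the other direction, 585 shCtrl regions were absent from shUbe2t #1 and 560 from shUbe2t #2. With the same number of intervals taken from each S9.6 list, there were 150 knockdown-shared regions, against 105 and 118 for the other pairs, and with a −log10 q of at least 5 there were 78, against 48 and 61.

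Regions called in all 3 libraries have a summit in each, and their signal can be set side by side. A call in every library is required, so regions below the threshold in any of them are missing from this set and the ratios describe its members alone. This measure was chosen after the data were examined. At the 125 such regions near gene ends and free of no-antibody intervals, the median depth-scaled pileup was 1.24 times that of shCtrl in shUbe2t #1 (SD of single regions 0.380) and 1.25 times in shUbe2t #2 (SD 0.387). It was higher than shCtrl in both knockdown libraries at 78 of the 125 and lower in both at 18. Away from gene ends the numbers were 37 and 16 of 78, and with a no-antibody interval 129 and 96 of 328. Both ratios share the same shCtrl library, so part of this agreement arises with no change. The ratio of shUbe2t #2 to shUbe2t #1 at these regions was 1.07. At the 78 regions away from gene ends the ratios to shCtrl were 1.07 and 1.08, and at the 328 regions with a no-antibody interval 1.05 and 1.01. Regions of one library are not independent replicates.

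Preset gene lists, 12 in number and fixed before the data were examined, were set against 10000 random lists of the same size, matched on gene length, in each of 7 sets of intervals or regions (84 comparisons). As a description of these libraries, 7 of the 84 counts were reached by at most 5% of random lists, and 5 of the 84 when random lists were also matched on biotype. Housekeeping and highly transcribed genes made up 4 of the 7, in the 3 S9.6 lists and in the regions common to all 3. These 4 sets share genes and are not separate results. Of the 30 genes on the housekeeping list, 6 held an interval in shCtrl (reached by 0 of 10000 random lists), 5 in shUbe2t #1 (0.03% of random lists), 5 in shUbe2t #2 (0.04%) and 0 without antibody. In the no-antibody list, 91.1% of random lists also held none. Eef1a1, a translation elongation factor, Hnrnpa2b1, an RNA-binding protein, and Hspa8, a constitutive HSP70, held regions of all 3 S9.6 libraries. None of the 30 was at a knockdown-shared region, and the same held for 86.8% of random lists. Tuba1a, an alpha-tubulin gene, was at a control-only region with a fold of 4.75, and 14.6% of random lists had at least 1 such member.

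Common fragile site genes and other very long genes, 27 in number, held an interval in 5 cases in shCtrl (6.63% of random lists), 5 in shUbe2t #1 (10.8%) and 6 in shUbe2t #2 (4.47%, or 5.52% with biotype matched). Without antibody the number was 4 (0.94% of random lists). Il1rapl1 and Lrp1b were in all 3 S9.6 lists. None of the 27 was at a knockdown-shared region, and the same held for 64.85% of random lists. Dlg2 was at a control-only region (fold 5.52) while another site in it was called in shUbe2t #1. At least 1 member at a control-only region was found in 63.8% of random lists.

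Of 28 Fanconi anaemia and crosslink repair genes, 1 held an interval in shCtrl (Slx4), 2 in shUbe2t #1 (Brca1 and Fancc) and 4 in shUbe2t #2 (Fancc, Fancl, Rfwd3 and Slx4). These counts were reached by 55.9%, 36.6% and 5.24% of random lists, the last by 8.62% with biotype matched. Fancc, a gene of the Fanconi core complex, had a knockdown-shared region in its body with folds of 6.02 and 4.81, and 25.3% of random lists had at least 1 such member. Of 34 genes of R-loop processing factors, none held an interval in shCtrl, 1 did in shUbe2t #1 (Ddx5) and 2 in shUbe2t #2. For these, 36.0% of random lists also held none in shCtrl, and 80.8% and 54.8% reached the counts of shUbe2t #1 and #2.

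The other lists gave 2 more members at knockdown-shared regions. They were Ube3a, an imprinted ubiquitin ligase gene (folds 4.74 and 4.23), and Egr1, an immediate early transcription factor gene (4.08 and 3.70), whose region lay 998 bp from the gene. At least 1 such member was found in 23.2% of random lists for the imprinted genes and 9.46% for the immediate early and p53 response genes. Neither these nor Fancc was counted at a −log10 q of at least 5. At control-only regions were the ribosomal protein genes Rpl37 (5.92) and Rpl4 (5.84), 2 of 77, a count reached by 3.96% of random lists, or 8.12% with biotype matched. Both regions lay nearer to an end of another gene, Card6 for Rpl37 and Snapc5 for Rpl4. Over single libraries, ribosomal protein genes with an interval numbered 2 in shCtrl (17.65% of random lists), 2 in shUbe2t #1 (Rpl15 and Rpl7, 33.3%) and 0 in shUbe2t #2. Of the 28 imprinted genes the numbers were 0, 3 (Snrpn, Snurf and Ube3a) and 1 (Ube3a) in the same order. Of random lists, 40.0% also held none in shCtrl, and 13.9% and 76.9% reached the counts of shUbe2t #1 and #2. Of the 25 immediate early and p53 response genes the numbers were 0, 1 (Fos) and 2 (Egr1 and Gadd45a). For these, 74.7% of random lists also held none in shCtrl, and 38.7% and 9.4% reached the counts of shUbe2t #1 and #2. Among 30 pluripotency genes only Klf2 held an interval, in shUbe2t #2, and among 25 germ cell genes only Hormad1, in the same library. The 25 early lineage markers held 1, Map2 in shUbe2t #1. The 58 replication-dependent histone genes held 1, H4f16 in shUbe2t #2, and the 21 abundant noncoding RNA genes 1, Gas5 in shUbe2t #2. For these lists, from pluripotency on, a count of 1 was reached by 26.46% or more of random lists.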

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

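Protein-coding gene ends and lists matched on biotype were chosen after the data were examined. Of 137 values under an alternative, 84 stayed within the 95% interval of the value reported or within 1.5 times of a count. Under the 6 alternatives that can change region counts, knockdown-shared regions outnumbered the larger other pair by 1.27 to 2.04 times. Under the 10 that can change locations, their share near gene ends exceeded that of control-only regions by 33.8 to 46.1 percentage points. The 53 values that moved follow, and the cause was not tested unless the setting itself shortens a list.

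With a −log10 q of at least 5 the lists held 600 (shCtrl), 696 (shUbe2t #1) and 770 (shUbe2t #2) intervals. The shares overlapping the no-antibody list were then 53.8%, 43.8% and 39.6%. Of shUbe2t #1 intervals 59.5% overlapped shCtrl and 63.5% shUbe2t #2, and of shUbe2t #2 intervals 55.3% overlapped shCtrl. There were 78 knockdown-shared and 131 control-only regions, 358 of all 3 libraries, 48 and 61 of shCtrl with shUbe2t #1 or #2 alone, and 204 and 266 of shUbe2t #1 or #2 alone. Near gene ends were 25.4%, 40.7% and 43.0% of the 3 lists and 67.1% of knockdown-shared regions, and 0 list genes were at knockdown-shared regions. With equal list lengths 50.6% of shUbe2t #1 and 51.3% of shUbe2t #2 intervals overlapped shCtrl, 150 regions were knockdown-shared, and 8 list genes were at control-only regions. On chromosomes 1 to 19 and X, 24.4% of shUbe2t #1 intervals overlapped the no-antibody list.

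After removal of intervals overlapping the no-antibody list, 26.0% of shUbe2t #1 and 25.9% of shUbe2t #2 intervals overlapped shCtrl, 39.5% of shUbe2t #1 intervals overlapped shUbe2t #2, 210 regions were in all 3 libraries, and the gene-end shares were 46.7%, 64.4% and 65.9%. With a window of 3000 bp the gene-end shares of shCtrl, shUbe2t #1, shUbe2t #2 and the no-antibody list were 48.6%, 63.2%, 64.8% and 27.3%, and those of knockdown-shared and control-only regions 83.3% and 45.9%. With 500 bp they were 31.7%, 47.7%, 49.1% and 10.4%, and 70.8% and 29.6%. With protein-coding gene ends they were 28.8%, 47.0%, 48.8% and 6.99%, and 26.5% for control-only regions. With 1 hairpin left out, the other alone gave 831 to 928 regions absent from shCtrl. Against lists not matched on length, 11 list comparisons were reached by at most 5% of random lists. Against lists matched on length and biotype the number was 5, within 1.5 times of the 7 reported. The alternatives planned for base composition were not run. No paired analysis was possible because each group holds 1 library. Depth limits single regions, since a median summit rests on 16 or 17 fragments in the S9.6 lists.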

Other observations

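The comparison of knockdown depth with shCtrl, the expected no-antibody calls at knockdown-shared regions and the preparation difference for gene-end location were tests chosen after the result was seen.

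Mitochondrial DNA gave 3 intervals in every library, covering 11249 bp in shCtrl, 11533 bp in shUbe2t #1, 11520 bp in shUbe2t #2 and 11211 bp without antibody. Knockdown-shared regions near gene ends were within reach of the ends of 2 or more genes in 68 of 181 cases (37.6%, 30.5 to 45.1), against 38 of 157 control-only regions (24.2%, 17.7 to 31.7). The 2 intervals overlap only between 30.5 and 31.7, which does not make the shares alike, and their difference was not tested. Protein-coding genes with an interval numbered 671 in shCtrl, 1084 in shUbe2t #1, 1186 in shUbe2t #2 and 160 without antibody, of 21883. Of the no-antibody intervals that overlapped no S9.6 interval, 65 were on placed chromosomes, and 2 of these were near a gene end (3.08%, 0.375 to 10.7).

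The no-antibody list was shorter than the S9.6 lists, and its library was shallower. Thinned to the depth of the no-antibody library, 818 (SD 12.6) of the shCtrl S9.6 intervals would still be called, against 516 no-antibody intervals and a limit of 619 set before the count was made. Lower depth alone does not account for the difference. Dependence on the antibody remains open as the biological explanation, from 1 library of each kind.

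More regions were shared by the 2 knockdown libraries alone than by either other pair. Greater depth is argued against, since the deeper knockdown library had 0.936 times the background of shCtrl. Longer knockdown lists could account for some or all of the excess. With equal lengths 150 knockdown-shared regions remained against 118 for the larger other pair. The limit set for this count, 150.1, covers counting error only and no difference between libraries. The count lay at that limit, which does not decide whether list length accounts for all of the excess. A preparation difference cannot be told apart from the knockdown, because there is 1 shCtrl library with S9.6. The smaller of the 2 median ratios to shCtrl at common gene-end regions, 1.24, would come from either.

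Knockdown-shared regions lay near gene ends more often than control-only regions. Weaker control-only calls are not ruled out. Among regions with a −log10 q of at least 5 in their strongest interval, 33.3% of 69 control-only regions (22.4 to 45.7) were near gene ends. The share was 75.4% of 130 knockdown-shared regions (67.1 to 82.5). A knockdown-shared region needed a call in both knockdown libraries, and either call could pass the filter. The filter therefore does not make the classes equally strong. Within control-only regions the filter did not raise the share, which was 35.5% without it. Cutting of open chromatin without antibody in the knockdown cells stays open. At the same signal per fragment the no-antibody library would hold 110 of the 181 regions and held 3, but it was made from shCtrl cells, in which these regions were by definition not called with S9.6. A preparation difference stays open too, with 1 shCtrl library and a larger median ratio at common gene-end regions of 1.25, against 1.01 in the same library at regions with a no-antibody interval. More R-loops at gene ends after loss of Ube2t is a hypothesis that these libraries cannot separate from them.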
